A study of Homo sapiens with 5 samples.

How the data were processed

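Total RNA from 5 cultures of LX-2 cells transduced with a HAND2 lentivirus was extracted with TRIzol and made into RNA-seq libraries with a commercial kit, per the labels' protocols. All 5 samples carried the same label, HAND2 overexpression, and formed 1 group with replicate numbers 1 to 5 taken from their titles. Each of the 2 deposited tables also held 5 columns of per-sample values that matched none of the 5 samples, and these were used in no step.

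The deposited gene table held whole-number read counts, 1 column per library, with no normalization. The deposited FPKM table held the same genes. In every library its values equalled the count divided by the gene length in the authors' table and by the library total, multiplied by 1 constant for all genes. The constants were 0.975, 1.01, 1.12, 0.964 and 1.02 in replicates 1 to 5. Their source is not given in the sources used here, and they cancel in any ratio taken within a library. Scaled to a geometric mean of 1, the constants were 0.9605, 0.9904, 1.1022, 0.9496 and 1.0044. The inverse TMM factors computed for the counts below were close, at 0.9741, 0.989, 1.0937, 0.9504 and 0.9986. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, without saying how each was used. The same notes name the mouse build mm10, which does not match the table, since its identifiers are human Ensembl genes. Of those, 58356 (94.8%) matched GENCODE release 29 by stable identifier, and 99.9% of the matched genes overlapped their GRCh38 position there, so coordinates are given on GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here.

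The table had 61657 entries. Of these, 124 had no gene name and were left out of library sizes and tests; they held 0.094% to 0.12% of the counts. The table's own biotype column marked all 61533 named genes as protein-coding, so gene types were taken from GENCODE release 29, in which 19871 of the matched genes are protein-coding. The planned design had assumed usable types in the table. Genes on the Y chromosome and XIST were left out of every list and every named result.

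Library totals over named genes ran from 16571634 to 19090070 counts. At this depth a count of 0 allows up to 3 counts, or 0.157 to 0.181 CPM (counts scaled to the library total), which covers counting error only. Levels of genes are the deposited FPKM, as mean and SD over 5 libraries, and a gene was called detected at an FPKM of at least 1 in every library. FPKM divides by the gene length in the authors' table, which for many genes is longer than a typical transcript. HAND2 is assigned 3601 bp against a median of 2058 bp for its annotated transcripts, GREM1 14784 against 2648 bp, TAGLN 6550 against 1227 bp and SMAD3 9981 against 1530 bp. Levels of such genes are lowered relative to genes whose assigned length is close to that of their transcripts.

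The main tests, gene lists and gene pairs, and all alternatives except those named as added, were chosen before the data were examined. Tests of possible causes for flagged results were chosen after those results had been seen. The 36 lists comprised 26 of cell programmes, 3 of RNA quality and 7 of other cell types, with 551 different genes in the table, of which 333 were detected. For each list the number of detected members and the median of mean FPKM were computed. The percentile of that median was taken among 10000 random lists of the same size drawn from protein-coding genes. The 32 gene pairs were compared by the mean log2 ratio of FPKM within libraries, with a pseudocount of 0.01 FPKM, and by an exact two-sided sign-flip permutation test over 32 sign patterns. Values were adjusted by the Benjamini-Hochberg method over pairs. Pairs in which a gene had under 10 counts in any library were not tested.

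Excess spread between replicates was tested on the counts with edgeR 4.0.16 in R 4.3.3. After filterByExpr, 13733 genes were normalized by TMM and fitted with an intercept only by glmQLFit with robust empirical Bayes. The quasi-dispersion of each gene was set against the fitted prior in an F test with 4.9 prior degrees of freedom, with adjustment over all genes at 0.05. List spread was the median log2 excess of the quasi-dispersion over tested members, ranked among 10000 lists matched on expression in 20 bins. Counts were simulated for the 13733 genes, with added spread in 200, and 13505 genes passed the filter again and were tested. The test recovered 14% of 100 genes with an added SD of 1 log2 unit and 68% of 100 genes with an SD of 2. Of 86 calls, 4 were false. The genes with added spread were drawn only from those with a mean above 5 CPM. The test therefore had little power at an added SD of 1 log2 unit, and it also missed many genes at an SD of 2. Libraries were compared by Pearson correlation of log2 CPM, by chi-square and by principal components.

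The rule for named genes took HAND2, both members of every pair, up to 4 genes with the highest mean FPKM of each list, the 10 most abundant protein-coding genes not encoded in the mitochondrion, up to 10 genes past the spread test and the 5 most abundant annotated transcription factors. ALDOA, IGF1, IGF2 and CD68 were named after their values had been seen. Some genes that the rule takes are not reported here.

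Alternatives included an FPKM minimum of 0.5 or 5, TPM, CPM in place of FPKM, pseudocounts of 0.1 and 1, DESeq2 1.42.0 size factors and dispersion outliers, limma 3.58.1 on log2(FPKM + 0.1), other filters and each replicate left out in turn. Added after the data had been seen were the removal of a smooth length trend from each library, the fit without libraries 3 and 4, and FPKM recomputed with the median length of each gene's basic transcripts in GENCODE release 29.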

Results

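RNA was sequenced from 5 cultures of LX-2 cells that carried a lentivirus overexpressing HAND2. LX-2 is an established human line of hepatic stellate cells, the pericytes of the liver, which store retinoids in healthy tissue and become matrix-producing myofibroblasts in fibrosis. HAND2 is a basic helix-loop-helix (bHLH) transcription factor best known from heart and limb development. The virus was given at a multiplicity of infection of 50 and the cells were collected 48 h later. The libraries held 16709737, 16571634, 17489426, 19090070 and 16745893 gene counts in replicates 1 to 5. The series design text describes 5 independent biological replicates per group, and the independence of the cultures rests on that text. The empty-vector cultures that it also describes are not analysed here, so the 5 libraries form 1 group and no level is set against a control. The data therefore give the levels of genes in HAND2-transduced cells, the ratios between genes within the same libraries, and the spread between cultures. They do not show which genes HAND2 changed. Levels are given as the deposited FPKM, which scale fragments by gene length, library total and 1 constant per library, as mean ± SD over the 5 libraries. A gene was counted as detected at an FPKM of at least 1 in every library, which 10524 genes reached. Of these, 9645 were protein-coding in GENCODE release 29. An FPKM of at least 0.5 in every library was reached by 12222 genes, so a gene called not detected can still have reads.

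The first question was how much HAND2 RNA the transduced cells held, and in what setting of partner factors. HAND2 (ENSG00000164107.9) lay at 8.17 ± 0.794 FPKM, with 392 to 630 counts per library, and ranked 4871 of the 10524 detected genes. Its paralog HAND1 had 1 or 2 counts in each library. Among bHLH factors that pair with HAND2 or resemble it, TWIST2 was at 18.4 ± 2.44 FPKM and TCF3, which encodes the E proteins E12 and E47, at 14.1 ± 1.01. TCF12 was at 4.11 ± 0.702 and TCF4 at 0.472 ± 0.0787. In all, 6 of 11 genes of the list of HAND2 and its partners were detected, among them GATA4, a zinc finger factor, at 7.60 ± 0.462 FPKM. Within libraries, HAND2 exceeded TCF12 by a log2 ratio of 1.0 ± 0.181 and TCF4 by 4.10 ± 0.192, in 5 of 5 libraries each. Its divergent antisense transcript HAND2-AS1 had 50 to 76 counts per library, and HAND2 exceeded it by a log2 ratio of 5.58 ± 0.151.

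HAND2 lies on chromosome 4, minus strand, from 173524969 to 173530229 (GRCh38), and 24.1% of its exonic bases in GENCODE release 29 are also exonic in HAND2-AS1 on the opposite strand. Gene counts do not separate reads of the lentiviral transgene from reads of the endogenous gene, and the strand setting of the counting is not given in the sources used here. The level depends on scaling and on the length assigned to the gene. It came to 28.8 when FPKM was rescaled to TPM, which gives every library the same total, and to 14.3 FPKM with the median length of its annotated transcripts. With those transcript lengths the ratio of HAND2 to TCF4 was 1.43 on the log2 scale and that to HAND2-AS1 was 2.19. In CPM (counts scaled to the library total), which does not divide by length, the ratio of HAND2 to TCF12 turned to -0.39, that to TCF4 was 1.11 and that to HAND2-AS1 was 3.09. With a pseudocount of 1 FPKM the last 2 were 2.64 and 2.98, and HAND2 to HAND2-AS1 was 4.98 with 0.1.

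The next question was which BMP and TGF-beta pathway genes these cells expressed, since the series title names the SMAD1/5/9 branch. BMP receptors phosphorylate SMAD1, SMAD5 and SMAD9, and TGF-beta receptors phosphorylate SMAD2 and SMAD3. SMAD5 was the main transcript of the first branch at 6.71 ± 0.911 FPKM, with SMAD9 at 1.17 ± 0.169 and SMAD1 at 0.318 ± 0.0685, the last from 24 to 55 counts per library. SMAD3 stood at 21.6 ± 3.33 FPKM and SMAD2 at 1.85 ± 0.146. SMAD5 exceeded SMAD9 5.70-fold and SMAD1 20.7-fold, and SMAD3 exceeded SMAD2 11.6-fold. Summed over each branch, SMAD1, SMAD5 and SMAD9 reached 8.20 ± 1.06 FPKM against 23.5 ± 3.45 for SMAD2 and SMAD3, a log2 ratio of -1.52 ± 0.119 (SD, n = 5) with the same direction in 5 of 5 libraries.

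Of the 15 BMP receptor and SMAD genes, 7 were detected, with a list median of 1.17 FPKM. ENG, a co-receptor, was the highest at 28.9 ± 1.73, followed by RGMB at 7.23 ± 0.762. The type I receptors BMPR1A and ACVR1 lay close together at 2.55 ± 0.383 and 2.46 ± 0.562 FPKM. Their log2 ratio was 0.07 ± 0.197, with BMPR1A the higher in 3 of 5 libraries. BMPR1B had at most 1 count in any library. The type II receptor BMPR2 was at 5.59 ± 1.41 FPKM, lower than its TGF-beta counterpart TGFBR2 at 12.1 ± 1.84 in 5 of 5 libraries, and TGFBR1 at 11.8 ± 1.65 exceeded BMPR1A 4.61-fold.

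BMP ligand RNA was scarce and antagonist RNA was not. Only 2 of 17 ligand-list genes were detected, with a list median of 0.0219 FPKM. They were BMP1 at 15.5 ± 0.474 and GDF11 at 7.89 ± 0.388. BMP1 encodes a procollagen protease and no BMP-type ligand. GDF11 encodes a ligand of the activin type, which signals mainly through the SMADs of the TGF-beta branch. BMP8B at 0.747 ± 0.136 and BMP4 at 0.708 ± 0.164 FPKM were below the detection level but not absent. BMP8B had a mean of 61.8 counts and BMP4 had 30 to 51 counts per library. At an FPKM minimum of 0.5, 4 of the 17 genes were detected. BMP2 had at most 1 count per library. Among 14 antagonists, 8 were detected. GREM1, which binds BMP2 and BMP4 outside the cell, was the highest at 65.2 ± 5.92 FPKM, ahead of FSTL1 at 43.2 ± 6.89, FSTL3 at 29.3 ± 3.38 and NBL1 at 25.7 ± 5.02. GREM1 exceeded NOG, at 1.19 ± 0.214, by a log2 ratio of 5.78 ± 0.223.

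Genes that BMP signalling is known to induce ranged widely, and 10 of the 16 in the list were detected. ID1, ID3 and ID2, which encode inhibitors of bHLH factors, lay at 85.2 ± 14.0, 61.5 ± 13.9 and 9.06 ± 1.38 FPKM. GATA2 was at 10.2 ± 0.656. ID1 exceeded ID3 by a log2 ratio of 0.48 ± 0.083 and ID2 by 3.23 ± 0.200. The inhibitory SMAD7 at 5.31 ± 0.670 FPKM was 6.82-fold above SMAD6 at 0.770 ± 0.0931.

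TGF-beta pathway genes were broadly expressed, with 15 of 19 detected and a list median of 6.95 FPKM. TGFB1 stood at 57.3 ± 2.44 FPKM, 7.67-fold above TGFB2 at 7.54 ± 1.25, and THBS1, which encodes an activator of latent TGF-beta, was at 21.8 ± 4.79. Among known targets of TGF-beta and of the co-activator YAP, 15 of 16 were detected, with a median of 40.3 FPKM. They included TGFBI at 290 ± 14.6, CCN1 at 273 ± 15.0, AXL at 235 ± 14.0 and CCN2 at 90.4 ± 10.8 FPKM. The medians of the signalling and target lists stood at the 98.7th and 100th percentiles of 10000 random lists of protein-coding genes of the same size. The receptor and SMAD list of the BMP branch stood at the 52.2nd, its response list at the 76.8th, the antagonists at the 62.8th and the ligands at the 1.9th. These ranks depended on the background. Against random lists of detected genes only, TGF-beta signalling stood at the 37.1st percentile and the 4 BMP lists at the 0th, while the TGF-beta and YAP targets stood at the 100th. The fixed lists keep their undetected members in that comparison.

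**Figure D1:**
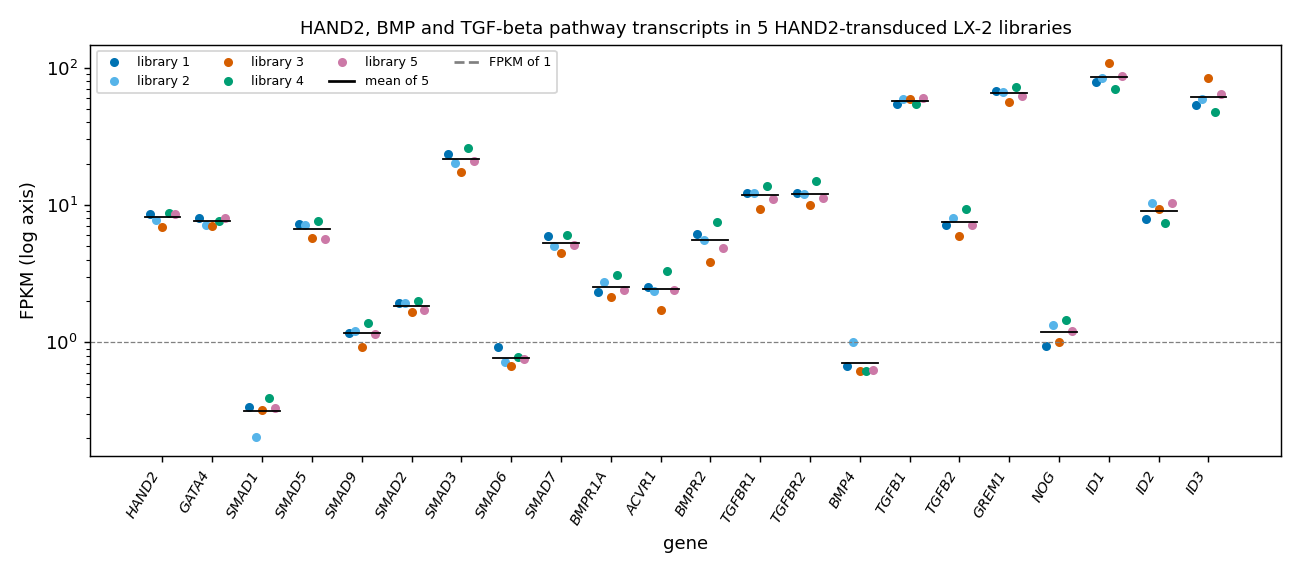
FPKM on a log axis of HAND2, GATA4 and genes of the BMP and TGF-beta pathways in the 5 HAND2-transduced libraries, 1 point per library, with a bar at the mean and a dashed line at an FPKM of 1. SMAD3 (mean 21.6) lies above SMAD5 (6.71), SMAD9 (1.17) and SMAD1 (0.318) in every library.

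Ratios between these genes depended on the gene length used, since FPKM divides by the length that the authors' table assigns. With median annotated transcript lengths the summed SMAD1, SMAD5 and SMAD9 ratio to SMAD2 and SMAD3 was -3.72, SMAD1 to SMAD5 was -2.94, SMAD1 to SMAD9 was -0.14, SMAD2 to SMAD3 was -4.44, GREM1 to NOG was 8.25 and BMPR1A to ACVR1 was -1.95, all on the log2 scale. In CPM the summed ratio was -2.02, SMAD2 to SMAD3 was -1.67, SMAD5 to SMAD9 was 3.15, SMAD6 to SMAD7 was -1.67, BMPR2 to TGFBR2 was -0.27, TGFB1 to TGFB2 was 2.05, ID1 to ID2 was 2.39 and GREM1 to NOG was 8.74. A pseudocount of 1 FPKM gave -2.54 for SMAD1 to SMAD5, 1.82 for SMAD5 to SMAD9, -0.72 for SMAD1 to SMAD9, -1.83 for SMAD6 to SMAD7 and 4.92 for GREM1 to NOG.

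A further question, also set by the title, was which extracellular matrix genes the cells expressed. The fibrillar collagens were uneven. COL1A1, which encodes the alpha 1 chain of type I collagen, stood at 134 ± 22.3 FPKM with 14468 to 28751 counts per library, whereas COL1A2, the gene of its partner chain, had 4 to 12 counts and 0.0452 ± 0.0164 FPKM. COL5A2 at 57.2 ± 9.71, COL5A1 at 24.3 ± 4.21 and COL3A1 at 4.79 ± 0.883 FPKM completed the 4 of 11 fibrillar collagens that were detected. COL1A1 exceeded COL3A1 by a log2 ratio of 4.80 ± 0.062, or 27.9-fold, in 5 of 5 libraries. COL1A1 lies on chromosome 17 from 50184101 to 50201632 and COL1A2 on chromosome 7 from 94394895 to 94431227 (GRCh38).

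Basement membrane genes were detected for 12 of 20 members. LAMC1 at 39.9 ± 7.33, AGRN at 31.6 ± 4.35, COL4A2 at 30.9 ± 4.10 and LAMB2 at 20.3 ± 1.75 FPKM led them. COL4A1, which shares a promoter region with COL4A2, was at 14.8 ± 2.93, lower than COL4A2 by a log2 ratio of -1.08 ± 0.0995. Of 12 other collagens 6 were detected, with COL6A2 at 53.4 ± 1.79, COL6A1 at 31.4 ± 2.86, COL12A1 at 9.03 ± 2.84 and COL8A1 at 5.42 ± 0.421. COL6A1 exceeded COL6A3, at 4.73 ± 1.2 FPKM, 6.79-fold. Matrix glycoproteins were represented by 17 of 25 genes, among them TGFBI, CCN1, SPARC at 178 ± 5.90 and FN1, the fibronectin gene, at 77.1 ± 20.1 FPKM.

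Enzymes that modify and crosslink collagen were detected for 17 of 19 members, with a median of 15.5 FPKM. LOXL2, a lysyl oxidase family member, was at 120 ± 7.27 FPKM, 34.0-fold above LOX at 3.57 ± 0.636. The prolyl hydroxylase subunit gene P4HB was at 88.5 ± 6.51, the collagen chaperone gene SERPINH1 at 52.5 ± 3.18 and the lysyl hydroxylase gene PLOD1 at 46.0 ± 2.45. Among matrix proteases and their inhibitors, 15 of 22 were detected. They included the metalloprotease inhibitor TIMP1 at 139 ± 17.1, the collagenase gene MMP1 at 129 ± 16.7 and TIMP2 at 76.0 ± 8.94 FPKM. TIMP1 exceeded TIMP2 by a log2 ratio of 0.87 ± 0.344 and the gelatinase gene MMP2 by 4.74 ± 0.163. MMP2 at 5.16 ± 0.194 FPKM was 6.40-fold below the membrane-bound MMP14 at 33.2 ± 2.54.

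The list medians of fibrillar collagens, basement membrane genes and other collagens stood at the 40.2nd, 75.3rd and 70.4th percentiles of the random lists, and those of matrix glycoproteins, collagen maturation and proteases at the 99.4th, 100th and 99.9th. Against random lists of detected genes the first 3 stood at the 0th, 0th and 0.1st, matrix glycoproteins at the 37th, proteases at the 69th and collagen maturation at the 96.4th. With median annotated transcript lengths the log2 ratio of COL6A1 to COL6A3 was 2.01. In CPM that ratio was 0.81, TIMP1 to MMP2 was 3.04 and TIMP1 to TIMP2 turned to -1.09.

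**Figure D2:**
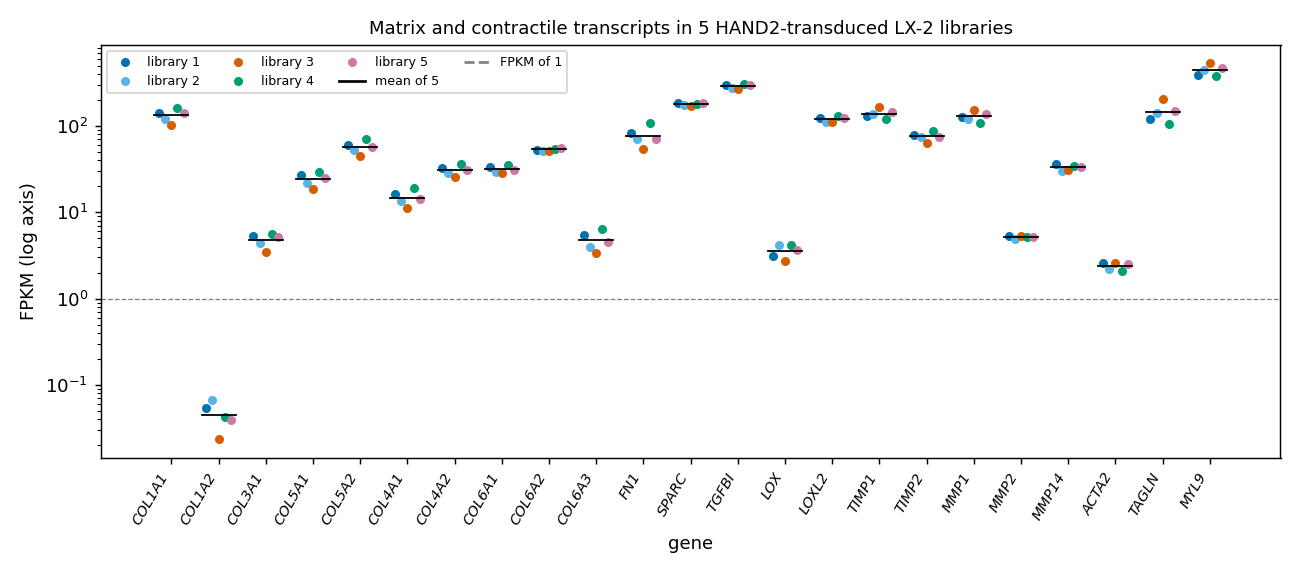
FPKM on a log axis of collagen, matrix, matrix enzyme and contractile genes in the 5 HAND2-transduced libraries, 1 point per library, with a bar at the mean and a dashed line at an FPKM of 1. COL1A1 has a mean of 134 FPKM and COL1A2 of 0.0452.

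The state of the cells along the stellate cell programme was the next question. Contractile myofibroblast genes were detected for 18 of 19 members, with a median of 86.5 FPKM at the 100th percentile of random lists of either kind. MYL9, a myosin light chain gene, was at 443 ± 62.8, VIM at 361 ± 21.9, FLNA at 256 ± 24.4, TPM2 at 198 ± 43.3 and TAGLN at 145 ± 39.2 FPKM. ACTA2, which encodes the alpha smooth muscle actin used as a marker of activated stellate cells, was at 2.40 ± 0.236 FPKM from 108 to 132 counts. It lay 58.8-fold below TAGLN in 5 of 5 libraries, at a log2 ratio of -5.88 ± 0.310, or -7.16 with median annotated transcript lengths and -7.02 in CPM. ACTA2 exceeded MYH11, a marker of mature smooth muscle at 0.0470 ± 0.0112 FPKM, by a log2 ratio of 5.41 ± 0.182. MYH11 had only 11 to 19 counts, and this ratio was 4.08 with a pseudocount of 0.1 FPKM, 1.69 with a pseudocount of 1 and 3.11 in CPM.

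Genes of stellate cell identity in tissue were mostly below the detection level, with 5 of 18 detected and a median of 0.124 FPKM at the 8.8th percentile of random protein-coding lists and the 0th of lists of detected genes. ECM1 at 16.2 ± 0.440, GATA4, NGFR at 4.34 ± 0.324 and PDGFRB at 3.66 ± 0.227 FPKM were the highest, and PDGFRA had 1 to 5 counts. The quiescence and retinoid storage list had 4 of 12 members detected and a median of 0.400 FPKM at the 24.5th percentile, or the 0th among detected genes. They were INSIG1 at 15.9 ± 1.34, PLIN2, which coats lipid droplets, at 5.61 ± 0.250, the pseudoreceptor gene BAMBI at 3.46 ± 0.405 and SREBF1 at 2.32 ± 0.187 FPKM.

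Genes of inflammation, growth and stress were also measured. Cytokine and chemokine genes were detected for 17 of 22 members, led by CXCL8 at 106 ± 24.3, IL1B at 90.3 ± 4.30, CCL5 at 87.3 ± 15.9 and IL11 at 56.6 ± 5.98 FPKM. CXCL8 exceeded IL6, at 9.98 ± 1.21, by a log2 ratio of 3.39 ± 0.426. Interferon response genes were detected for 13 of 24 members, with ISG15 at 168 ± 53.1, BST2 at 50.4 ± 9.52, IFI6 at 49.8 ± 12.3 and OASL at 18.1 ± 4.0 FPKM. All 20 proliferation genes were detected, with a median of 55.5 FPKM, and CCNB1 at 356 ± 33.8, PCNA at 301 ± 11.7, MCM7 at 160 ± 19.6 and BIRC5 at 94.5 ± 19.8 were the highest. Of 18 unfolded protein response genes 17 were detected, led by CALR at 601 ± 62.8, ATF4 at 153 ± 21.3, PDIA4 at 128 ± 5.42 and HSPA5 at 125 ± 7.29 FPKM. The medians of the cytokine, interferon, proliferation and unfolded protein lists were at the 98.5th, 77.7th, 100th and 100th percentiles of random protein-coding lists. Against lists of detected genes the cytokines stood at the 17.8th and the interferon genes at the 0th, while proliferation was at the 100th and unfolded protein genes at the 99.9th.

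Across the whole transcriptome abundant protein-coding mRNAs not encoded in the mitochondrion included TMSB10 at 7164, FTL at 3201, GAPDH at 3029, ACTG1 at 1867, MT2A at 1627, ACTB at 1521, LGALS1 at 1479, RPL41 at 1288 and TPI1 at 1215 FPKM. Among genes that the authors' table annotates as transcription factors, the highest were HMGA1 at 377 ± 34.6, YBX1 at 332 ± 25.6, MYBL2 at 164 ± 18.6, ATF4 at 153 ± 21.3 and GTF3A at 128 ± 18.2. All 15 housekeeping genes and all 13 mitochondrial mRNAs were detected, with medians of 222 and 1214 FPKM, and MT-CO1 was the highest of the latter at 3770 ± 510. Mitochondrial genes took 1.69% to 2.19% of the counts of a library. All 6 histone genes were detected, with H1-2 at 154 ± 39.3 and H2AC6 at 32.5 ± 5.05 FPKM.

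Markers of other cell types were measured to give the background. Some of them cannot serve for this, since they are also in lists above. Among these are ACTG2 and CNN1, in the contractile list, and FBLN2, in the matrix glycoprotein list. The hepatocyte list had 3 of 17 members detected, SERPINA1 at 6.51 ± 0.618, CPS1 at 2.51 ± 0.529 and ASGR1 at 1.69 ± 0.302 FPKM, and a list median of 0.00473. Of cholangiocyte markers 2 of 11 were detected, SOX9 at 5.50 ± 0.723 and KRT7 at 2.49 ± 0.685. Endothelial markers were detected for 1 of 13, TIE1 at 18.6 ± 0.742, and macrophage and leukocyte markers for 3 of 15, CD14 at 2.72 ± 0.274, CD3D at 2.08 ± 0.580 and ADGRE1 at 1.79 ± 0.547. Portal fibroblast and mesothelial markers were detected for 6 of 14, led by KRT18 at 221 ± 44.9, KRT8 at 87.5 ± 16.7, THY1 at 19.0 ± 2.45 and FBLN2 at 17.8 ± 1.99 FPKM. Vascular smooth muscle markers were detected for 4 of 10, ACTG2 at 32.1 ± 4.22, CNN1 at 15.7 ± 1.89, SMTN at 13.8 ± 0.531 and SYNM at 1.51 ± 0.369. None of 8 kidney line markers, which stand for cells that package lentivirus, was detected, and their list median was 0.0218 FPKM. No cell type was called from these levels.

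The gene pairs were compared by an exact sign-flip permutation test of the mean log2 ratio over the 5 libraries, two-sided. Of 32 pairs fixed before the data were examined, 27 had at least 10 counts in both genes in every library, and 26 of these 27 had the same direction in 5 of 5 libraries. Each of the 26 reached an exact p = 0.063, the smallest that 5 libraries allow, and a Benjamini-Hochberg adjusted value of 0.0649 over the 27 pairs. The design therefore cannot pass a threshold of 0.05 for any pair. BMPR1A against ACVR1 had an exact p = 0.438 and an adjusted value of 0.438. The pairs of HAND2 with HAND1, COL1A1 with COL1A2, BMPR1A with BMPR1B, BMP4 with BMP2 and PDGFRB with PDGFRA were given as levels only.

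The last question was how far the 5 cultures differed from each other. The Pearson correlation of log2 CPM across genes ranged from 0.976 between libraries 3 and 4 to 0.994 between libraries 1 and 4. No pair of libraries agreed within sampling noise, since the chi-square statistic of counts divided by its degrees of freedom ran from 6.08 to 82.7, so none was the same library deposited again. This does not separate independent cultures from separate preparations of 1 culture. Libraries 3 and 4 differed most, and the difference followed gene length. Over 5 equal bins of the 13733 tested genes with median lengths of 1855, 3524, 5118, 7139 and 11507 bp, the median log2 difference of library 4 minus library 3 was -0.40, -0.15, 0.02, 0.17 and 0.38. Spearman's rho between this difference and length was 0.489 across genes, which are not independent replicates.

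**Figure D3:**
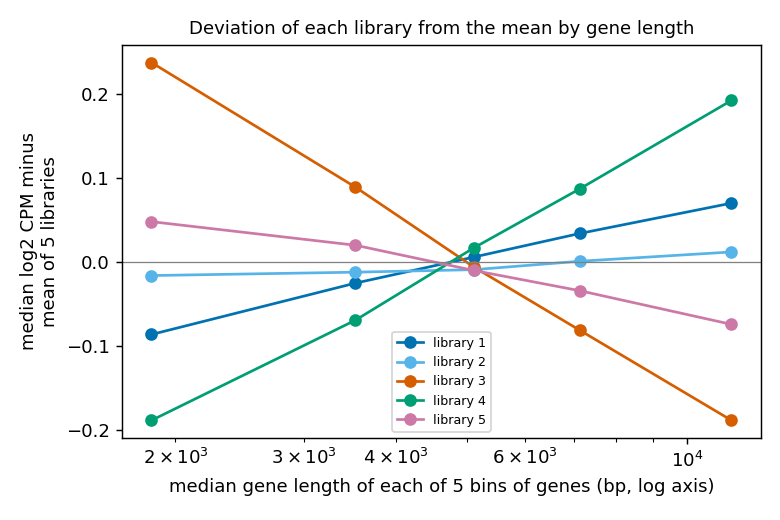
Median deviation of each library from the mean of the 5 (log2 CPM) for 5 equal bins of the tested genes by length, plotted against the median gene length of each bin in bp on a log axis, 1 line per library. Library 3 runs from 0.24 in the shortest bin to -0.19 in the longest, and library 4 from -0.19 to 0.19.

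Gene lists deviated in libraries 3 and 4 in both directions. The median log2 deviation of fibrillar collagens was -0.38 in library 3 and 0.29 in library 4, that of basement membrane genes -0.28 and 0.30, that of matrix glycoproteins -0.31 and 0.21, that of TGF-beta signalling genes -0.28 and 0.28 and that of BMP receptors and SMADs -0.24 and 0.29. Interferon response genes deviated the other way, by 0.25 in library 3 and -0.14 in library 4. So did the quality and other-cell-type lists of histone genes at 0.22 and -0.24, housekeeping genes at 0.20 and -0.14, portal fibroblast and mesothelial markers at 0.31 and -0.10 and macrophage and leukocyte markers at 0.43 and -0.23. Mitochondrial mRNAs, which are short, deviated by -0.28 and 0.09, against the direction of the length pattern. HAND2 itself deviated by 0.11, -0.07, -0.24, 0.12 and 0.08 in libraries 1 to 5, and by 0.12, -0.06, -0.32, 0.18 and 0.07 once a smooth trend in length had been taken out of each library. Contractile genes deviated by 0.04 and -0.08 and proliferation genes by 0.01 and -0.02 in libraries 3 and 4.

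No gene passed the test for excess spread between replicates in edgeR at a Benjamini-Hochberg adjusted p of 0.05, and 514 of 13733 had an unadjusted p under 0.05. That is a smaller share than the 0.05 such a test gives where no gene has excess spread. The prior was fitted to these same genes. No member of any of the 35 lists with at least 3 tested genes passed, and none passed when adjusted over the list alone. DESeq2 marked 15 genes as dispersion outliers and limma called 0. The edgeR count was 12 without replicate 3 and 6 without replicate 4. The typical biological coefficient of variation was 14.2%, and 12% with the length trend removed. The spread of the 35 lists was ranked against 10000 lists matched on expression, as a description, since members of a list can vary together. Interferon response genes stood at the 99.5th percentile, basement membrane genes at the 97.8th, TGF-beta signalling at the 97.6th and matrix glycoproteins at the 97th. Collagen maturation at the 0th, stellate identity at the 0.8th and proliferation genes at the 1.5th varied least, and stood at the 14th, 6.9th and 26.4th with the length trend removed. The lowest lists were then unfolded protein response at the 1.3rd, from the 26.1st before, quiescence at the 2.1st, from the 6th, and immediate early genes at the 2.7th, from the 18.5th. With the length trend removed, interferon response genes moved to the 51.4th percentile, basement membrane genes to the 84.4th and TGF-beta signalling to the 87.2nd, while matrix glycoproteins stood at the 97.9th and mitochondrial mRNAs, at the 72.5th before, at the 99.9th.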

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

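The patterns in libraries 3 and 4, COL1A2 and ALDOA were seen first, and tests of them were chosen afterwards. The tests of library size and of overlapping exons were set before their own values were seen. Those of gene length and GC content, and the overlap of coding bases, were chosen only after the result was seen. With 210 values examined, chance alone puts about 5% of them this far from the rest, and 5 stood apart.

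BMP4 was at 0.998 FPKM in library 2 and between 0.619 and 0.678 in the other libraries. H2BC4, a histone gene, was at 5.36 FPKM in library 2 against 3.07 to 3.71. KRT7 was at 3.68 FPKM in library 3 against 1.99 to 2.41, and THY1 at 23.1 FPKM in library 3 against 16.6 to 18.4. The geometric mean of the kidney line markers was 0.0803 FPKM in library 4 against 0.0509 to 0.0589 in the others, all far below the detection level. Entries with no gene name, which entered no comparison, held a mean of 0.106% ± 0.010 of the counts (SD, n = 5), above what a count of 0 allows. Of these reads 52% fell in 1 entry of 5407 bp, from 130203 to 135609 on an unplaced scaffold, with a mean of 9559 counts.

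Libraries 3 and 4 stood furthest apart of the 5, with a Pearson correlation of 0.976, and the first principal component, which took 60.4% of the variance, placed them at opposite ends. Every library was thinned to the smallest total as a test of library size. The SD of the difference across genes stayed at 100.5% of its value before thinning. That difference was already scaled to library size and thinning only adds sampling noise, so the SD could hardly have fallen. The test therefore cannot say whether library size contributed. GC content was tested only on the variance left after length, of which a smooth trend in GC removed 3.3%. GC therefore added little beyond length, and any part of the difference shared by GC and length was not tested. A smooth trend in gene length removed 23.7% of the variance, between the 5% set as too little and the 30% set as enough, so length bias may contribute but cannot be told apart from a difference between cultures that is related to length. No biological explanation was tested, because both libraries belong to the same group.

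COL1A2 was nearly absent, at 4 to 12 counts, beside 14468 to 28751 for COL1A1. In GENCODE release 29, 0.0% of COL1A2 exonic bases lie in exons of another gene, which argues against loss of reads to an overlapping gene. The annotation used for the counting is not given, so a gene that overlaps only there was not checked. Whether the low level belongs to the line, to its culture or to HAND2 stays open without control libraries, and no biological explanation was tested.

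ALDOA, which encodes the aldolase of glycolysis, lay at 5.23 ± 0.479 FPKM, whereas TPI1, GAPDH and ENO1 of the neighbouring steps were at 1215, 3029 and 513. In GENCODE release 29, 53.5% of its exonic bases lie in exons of other genes, above the 50% set beforehand, and so do 93.8% of its coding bases, so reads lost as ambiguous are a candidate explanation of the low level. An overlapping gene on the same strand, AC093512.2, shares 42.3% of the exonic bases and had a mean of 143 counts against 342 for ALDOA. Reads discarded as ambiguous were not measured, and no biological explanation was tested. Among 550 list genes with annotated exons, IGF1, IGF2 and CD68 were the others with over 50% of their bases shared, so their low levels carry the same limit.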

How the results depend on the processing

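The removal of the length trend, the fit without libraries 3 and 4 and the use of transcript lengths were chosen after the data had been seen. Each other alternative was planned. No paired analysis was possible because the 5 libraries form 1 group.

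The number of detected genes was 5946 at an FPKM minimum of 5 and 12222 at 0.5. It was 13316 at a TPM minimum of 1 and 12570 when 1 library sufficed, and lay between 10581 and 10693 with 1 replicate left out. FPKM summed to only 256343 to 339081 per library, so an FPKM of 1 is a stricter cut than a TPM of 1. Every count of detected list members rests on that cut. HAND2 was at 28.8 after rescaling to TPM and at 14.3 with transcript lengths, and between 8.01 and 8.47 FPKM with 1 replicate left out. Over all pairs and alternatives, 238 values kept their direction and 3 turned. For the 26 pairs with the same direction in 5 of 5 libraries, a pseudocount or leaving out 1 replicate could not turn the mean. Only CPM and transcript lengths, each given for 27 pairs, could have turned them. HAND2 to TCF12 became -0.39 and TIMP1 to TIMP2 -1.09 in CPM, which does not divide by length, and BMPR1A to ACVR1 became -1.95 with transcript lengths. Of 27 pairs, 15 moved over 1.5-fold in CPM and 10 with transcript lengths. A pseudocount of 1 moved 8 of 26 and one of 0.1 moved 2 of 26. Leaving out 1 replicate moved no pair by more than 0.17 on the log2 scale.

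The edgeR count of genes with excess spread was 321 with no filter on low counts, 2 with the length trend removed, 35 without libraries 3 and 4, and from 0 to 12 with 1 replicate left out, with 12 without replicate 3 and 6 without replicate 4. It was 0 with DESeq2 size factors, a filter of 5 CPM or no robust fit, and limma gave 0. DESeq2 marked 15 dispersion outliers. The cause of these differences was not tested. The number of lists above the 95th percentile of spread was 4, 2 with the length trend removed, and 3 to 5 with 1 replicate left out. Among list percentiles of level, 24 of 36 moved by over 5 points when the random lists held detected genes only, a higher background. Many moved far, with TGF-beta signalling from 98.7 to 37.1, cytokines from 98.5 to 17.8, Wnt from 88 to 0.2, PDGF genes from 87.7 to 0.3 and HAND2 partners from 82.3 to 3. Depth limits genes near the floor, among them COL1A2, HAND1, BMP2, BMPR1B and PDGFRA.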

Other observations

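No test in this part was run after its result was seen, since it gives levels only. Growth factor and developmental pathway genes not described so far were unevenly expressed. Of 20 PDGF and growth factor genes 12 were detected, with PDGFC at 14.7 ± 1.1, VEGFC at 14.4 ± 2.28, FGFR1 at 12.7 ± 0.889 and FGF2 at 12.4 ± 1.28 FPKM (SD, n = 5). Their median of 3.20 FPKM stood at the 87.7th percentile of random protein-coding lists and at the 0.3rd of lists of detected genes. Wnt pathway genes were detected for 14 of 23 members, with a median of 3.08 FPKM at the 88th percentile, or the 0.2nd among detected genes. The secreted Wnt inhibitor genes DKK1 at 265 ± 10.8, DKK3 at 35.5 ± 1.19 and SFRP1 at 33.7 ± 5.88 stood beside CTNNB1, the beta-catenin gene, at 34.9 ± 1.17. Hedgehog and Notch genes were detected for 8 of 20 members, with a median of 0.700 FPKM at the 35.2nd percentile, or the 0th among detected genes, led by NOTCH2 at 18.3 ± 5.50, SMO at 9.73 ± 0.473, HES1 at 5.82 ± 0.192 and NOTCH1 at 2.28 ± 0.503.

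Stress and metabolic genes were detected in most cases. The p53 and apoptosis list had 12 of 15 members detected, with BAX at 65.9 ± 12.7, PMAIP1 at 39.7 ± 4.85, TNFRSF10B at 31.0 ± 3.06 and CDKN1A, which encodes the cell cycle inhibitor p21, at 31.0 ± 4.54 FPKM. In the hypoxia and glycolysis list 13 of 16 were detected, with GAPDH at 3029 ± 638, ENO1 at 513 ± 80.5, PGK1 at 373 ± 77.3 and LDHA at 223 ± 15.2. Immediate early genes were detected for 11 of 16 members, with FOSL1 at 127 ± 7.37, IER3 at 103 ± 18.4, JUN at 78.6 ± 3.03 and DUSP1 at 49.3 ± 5.01. The medians of these lists were 7.54, 14.0 and 7.70 FPKM, at the 98.4th, 99.9th and 98.9th percentiles of protein-coding lists. Among lists of detected genes they stood at the 47.3rd, 92.3rd and 47.7th. Of the 6 histone genes, H2BC4 and H2AC20 were at 3.82 ± 0.891 and 2.94 ± 0.772 FPKM, and the list median of 3.38 stood at the 72.2nd percentile, or the 5.9th among detected genes.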
